A study of Homo sapiens with 2 samples.

How the data were processed

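RNA of cells labelled Jurkat was measured on Illumina HT12 arrays in 1 sample treated with Me6TREN for 24 hours and 1 control sample given phosphate-buffered saline, and the group of each sample came from its treatment label. The dose was not given in the sources used here. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, RNA was extracted with Trizol and cleaned up with a DNase step, and biotin-labelled cRNA was made with the Ambion MessageAmp kit.

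The authors deposited a table that was not normalized between arrays. Per the file headers it holds for each array the mean bead signal of each probe, a linear intensity with the background still in it, the detection p-value and the number of beads. The deposited detection p-values move in steps of 1 in 770, the rank of a probe among the array's negative controls. Each detection column followed the signal of its own block without exception, which settled its array. A deposited series matrix holds processed intensities of the same arrays. Each of its columns was, to within 0.0131, the array's signal times a factor (0.951 for the control and 1.05 for Me6TREN) plus a constant of −228.0 or −269.5, so that both columns had the mean 1297. Its medians were 30.9 and 28.8, its scale is linear, its values are not centred on genes, and its columns rise with the signal. The authors' software, background step and normalization are not given in the sources used here.

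Signals were corrected and normalized with limma 3.58.1 in R 4.3.3 by the neqc method, which estimates the background from negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was called detected at a detection p-value under 0.01, which corresponded to lowest detected signals of 333.4 on the control array and 350.5 on the Me6TREN array. These limits set the precision at the dim end, and the robust standard deviation of log2 ratios over genes ran, over 10 bins of mean signal, from 1.11 in a dim bin to 0.38 in the brightest. Median signals were 272.1 and 283.1 and the 75th percentiles 466.7 and 397.5. Quantile normalization gives both arrays the same distribution of signals, so it removes any array-wide difference in RNA content and compresses or stretches ratios where the raw distributions differ.

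Genes were named through the platform annotation of GEO, which gave 1 symbol for 30113 probes and several for 8 and did not list the others, so that 17209 probes had no symbol of their own and are unnamed here. Of the named probes, 30074 were matched by Entrez ID to the RefSeq gene table of assembly GRCh38.p14, and no symbol needed an update. No coordinates are given because no genome build is named in the files. Each gene was represented by its brightest probe among those detected on at least 1 array. Where a gene was detected on 1 array only, the ratio is a bound against the higher of the lowest detected signal and the probe's own signal on the other array, written as at least N-fold. Ratios are Me6TREN over control. Levels of genes that mark the sex of a donor are not reported here.

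With 1 array per group no test was made. Genes were counted at a fixed 2-fold threshold. For each of 31 gene lists, the median log2 ratio was set among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins, and a list was said to stand apart below the 2.5th or above the 97.5th percentile. List members are called higher or lower at 1.5-fold. The percentile describes these 2 arrays and is not a p-value. The lists, 6 marker sets of other cell types, the thresholds, 9 alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest genes detected on both arrays, the 3 largest bounds each way, up to 4 members of each list with the largest ratios, and CXCR4, CXCL12, MMP9, MMP2, TIMP1, JUN, FOS, MYC, CD3E, GAPDH and ACTB. Genes named outside the rule are marked as chosen after their values were seen.

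The alternatives were no background correction, normexp over all probes with an offset of 50, median centring in place of quantile normalization, the series matrix values with a floor at 99.9, a detection threshold of 0.05, only genes detected on both arrays, no filter on detection, the mean of a gene's probes, and a neqc offset of 50. The floor is the higher of the 2 arrays' lowest detected series matrix value. The steps were tested on simulated data for this comparison with 10111 measured genes, of which 200 were changed. Genes simulated at a log2 ratio of 2.0 were counted as 2-fold in 100.0% of cases and those at 1.3 in 86.0%; for −2.0 and −1.3 the shares were 98.0% and 88.0%. Unchanged genes were counted in 0.49% of cases. Of 100 unchanged lists of 25 genes, 3.0% fell outside the central 95%. The simulation used noise of 1 fixed size, changed bright genes only and held no array-wide shift or difference between cultures. These shares therefore check the steps and are not error rates of the real counts. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.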

Results

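Gene expression was measured in cells labelled Jurkat, a line derived from a human T cell leukaemia, after 24 hours with Me6TREN or with phosphate-buffered saline as the control. Me6TREN is a small branched amine that binds metal ions and is known as an agent that mobilises blood-forming progenitor cells. Each group had 1 Illumina HT12 whole-genome array, so no value has a standard deviation or a p-value, and each difference is between 2 arrays without a replicate check. The control array detected 15363 of 47322 probes (32.5%) and the Me6TREN array 13656 (28.9%), with a median of 22 beads behind each probe on both. Of 20046 named genes, 9410 were detected on at least 1 array and 7834 on both. The number of arrays, not the number of probes, limits the precision.

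The array from Me6TREN-treated cells showed higher signals of immediate early, heat shock and histone genes and of the small RNAs U1 and U3, and many of these histone and small RNA transcripts have no poly(A) tail. It showed lower signals of genes of DNA replication and, less firmly, of ribosome assembly, a list that did not stand apart over genes detected on both arrays. JUN, a subunit of the AP-1 transcription factor, was not detected on the control array and was at least 66.0-fold higher with Me6TREN. Its partner FOS was 17.5-fold higher, the heat shock gene HSPA6 30.9-fold higher, the stress gene GADD45B 17.3-fold higher and TAGAP, a GTPase-activating protein of activated lymphocytes, 41.0-fold higher. As deposited, with the background in them, the control and Me6TREN signals were 317.5 and 5957.4 for JUN and 419.2 and 2494.6 for FOS. The size of such ratios therefore depends on the background correction. HPS6, a subunit of a complex that builds lysosome-related organelles, was 27.4-fold lower. In all, 634 genes were at least 2-fold higher and 935 at least 2-fold lower, of which 537 and 741 were detected on both arrays.

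The split between higher and lower genes depended on how the arrays were scaled. With quantile normalization, 40.4% of the genes past 2-fold were higher, and the median log2 ratio of all measured genes was −0.12. With median centring in its place, 950 genes were higher and 769 lower (55.3% higher, median log2 ratio 0.08). With the authors' series matrix values, 283 were higher and 2332 lower (10.8% higher, median log2 ratio −0.43). Gene lists are therefore set against random lists of the same mean signal, which share the array-wide shift.

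Among genes detected on both arrays, the U3 small nucleolar RNAs, which guide the cleavage of ribosomal RNA precursors, led with SNORD3C at 94.9-fold, SNORD3A at 57.1-fold and SNORD3D at 54.4-fold higher. RNVU1-7 and RNU1-3, which encode U1 spliceosomal RNA, were 20.8-fold and 18.6-fold higher. HSPA7, a near-identical copy of HSPA6, was 18.1-fold higher. The members of each of these families share nearly all of their sequence, so the assignment to 1 copy is uncertain. The ratios of the U3 and U1 RNAs are differences in signal. Whether more RNA without a poly(A) tail was labelled on the Me6TREN array stays open. Among genes detected on the Me6TREN array alone, DRD3, a dopamine receptor, was at least 16.8-fold higher and SNORA28, a small nucleolar RNA, at least 12.5-fold higher.

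After HPS6, the lowest ratios were those of FBXL18, an F-box protein (11.3-fold lower), LIAT1 (10.5-fold lower) and UBASH3B, a phosphatase of receptor signalling (10.2-fold lower). The mitochondrial glutamate carrier SLC25A22 was 8.80-fold lower, CPT2 of mitochondrial fatty acid import 8.76-fold lower and the clock gene PER2 8.68-fold lower. RPUSD2, EID2 and ANKRD46 were 7.92-fold, 7.73-fold and 7.35-fold lower. Among genes detected on the control array alone, ZC3H4, a protein of transcription termination, was at least 14.6-fold lower, the chromatin reader JADE2 at least 9.97-fold lower and the RNA polymerase II regulator RPRD2 at least 9.93-fold lower.

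**Figure D1:**
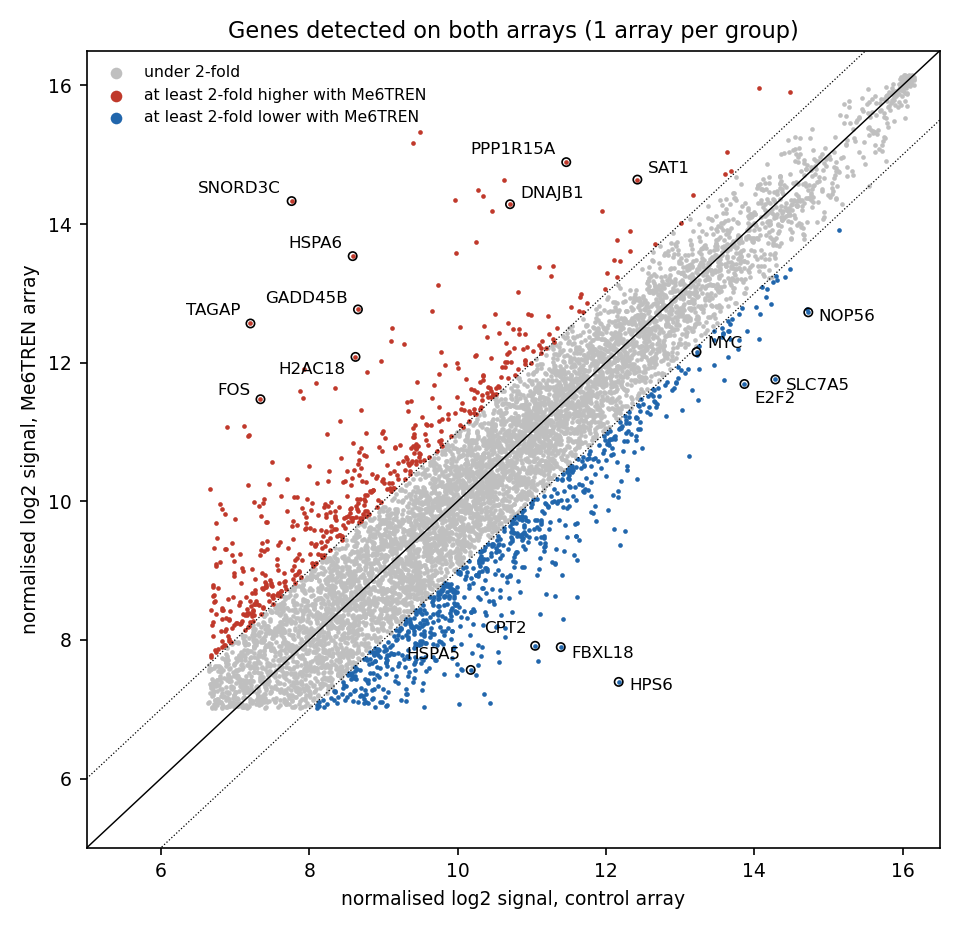
Normalised log2 signals of the 7834 genes detected on both arrays, control on the x axis and Me6TREN on the y axis, 1 point per gene. The solid line marks equal signals and the dotted lines a 2-fold difference; FOS, TAGAP and SNORD3C lie far above the diagonal and HPS6 far under it.

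Both arrays detected B lineage genes at high signals and few T-restricted genes. CD3E, a chain of the T cell receptor complex, was not detected on either array, nor were LCK, CD5 and CD7. Of 18 T-restricted genes with a probe, 4 (22.2%) were detected on both arrays, against 39.1% of all named genes. These 4 were CD247, SIT1, CD28 and SH2D1A. On at least 1 array, 9 of the 18 were detected, against 9410 of 20046 named genes. By count the shortfall was therefore in detection on both arrays. LAT and CD3G, detected on the control array alone, had signals of 336.3 and 348.0 there, near its lowest detected signal of 333.4. CD2 and ZAP70, detected on the Me6TREN array alone, had signals of 353.3 and 374.3, near its limit of 350.5. CD3D lay farther above, at 587.4 on the control array. Those 18 genes were picked after the values were seen from the T cell receptor list, of which 11 of 33 genes with a probe (33.3%) were detected on both arrays. CD3D was detected on the control array alone and was at least 2.26-fold lower with Me6TREN. Of 5 B cell markers with a probe, CD79A, CD79B, MS4A1 and BLK were detected on both arrays and PAX5 on neither. The signal of CD79A, part of the B cell receptor, was 32313 on the control array and 33455 on the Me6TREN array, against lowest detected signals of 333.4 and 350.5. Of 21 further B lineage genes, chosen after the values were seen, 19 were detected on both arrays, among them CD74, HLA-DRA, BTK and EBF1. The log2 ratio of CD79A was −0.03, that of CD79B −0.26 and that of BLK −0.27, while that of MS4A1 was 0.45. The sign of CD79A and CD79B turned with median centring and with the series matrix values, and that of MS4A1 turned with the series matrix values.

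**Figure D2:**
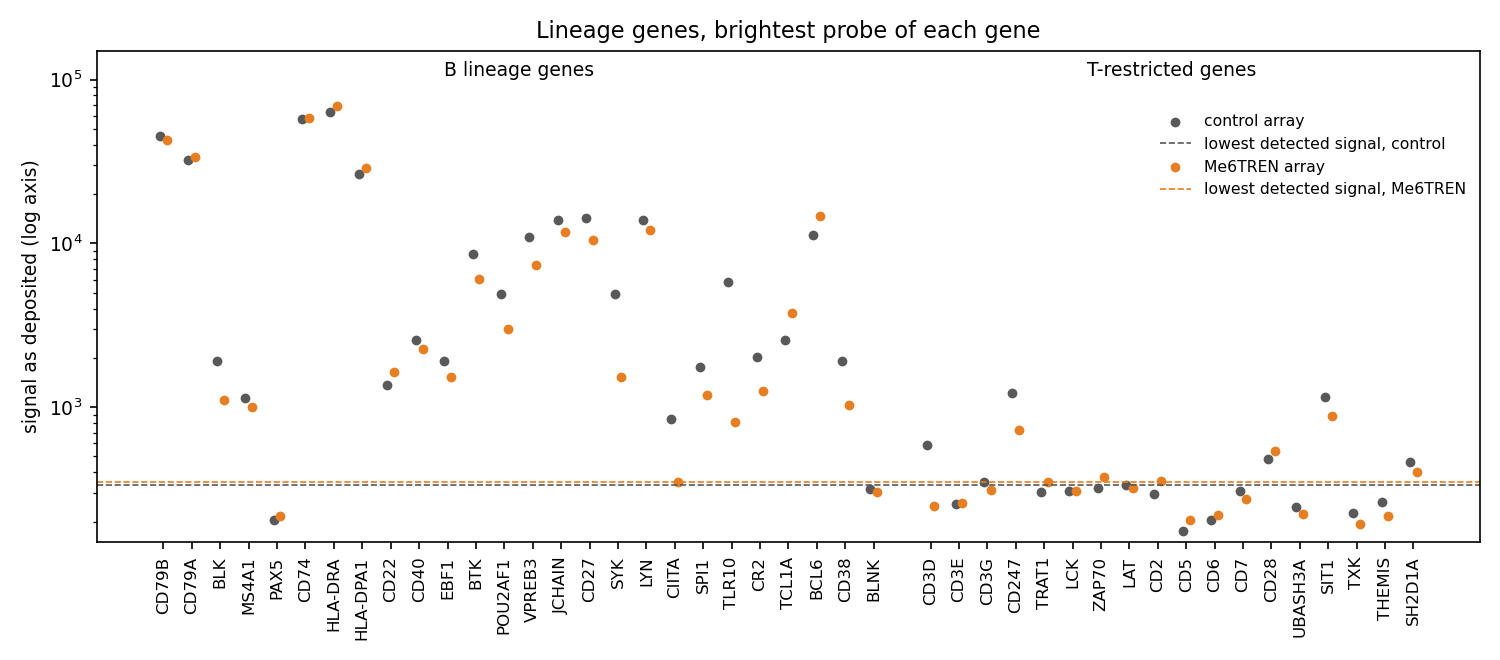
Signals as deposited, on a log axis, of the brightest probe of each B lineage gene (5 fixed markers, then 21 genes added after the values were seen) and of 18 T-restricted genes, on the control and Me6TREN arrays. The dashed lines mark the lowest detected signal of each array (333.4 and 350.5); CD3E, LCK, CD5 and CD7 lie under both lines.

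Markers of other cell types were mostly at background. Of 8 myeloid markers with a probe, 4 were detected on at least 1 array and CD68 alone on both, with a log2 ratio of 0.73. CD14 and LYZ were detected on the Me6TREN array alone, with lower bounds of 0.69 and 0.38 for their log2 ratios. Among 6 erythroid markers with a probe, HBB was detected on both arrays, at a log2 ratio of −0.11. KRT18 was the 1 epithelial marker detected, on the Me6TREN array alone, and the natural killer cell marker NKG7 was detected on both arrays with a log2 ratio of 0.10, which turned to −0.45 with the series matrix values. None of the 6 fibroblast markers was detected.

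Of the 31 gene lists, 7 had a median log2 ratio above the central 95% of matched random lists and 6 below it. Of 31 lists of genes drawn independently, 1.55 would fall outside. Genes of 1 list can vary together between any 2 cultures, so the comparison with 1.55 is not a test. The AP-1 and immediate early genes, which respond within minutes to growth factors and stress, had a median log2 ratio of 1.19 (1.04 with undetected genes at their bound, 0.38 to 1.38 under the 9 alternatives), above all 10000 random lists. Of 24 measured members, 16 were at least 1.5-fold higher and 4 at least 1.5-fold lower. Besides JUN and FOS, the phosphatase gene DUSP1 was 12.2-fold higher and PPP1R15A, which restores translation after stress, 10.8-fold higher. MYC, a driver of cell growth, went the other way and was 2.10-fold lower (log2 ratio of −0.52 by its other detected probe).

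Replication-dependent and related histone genes had the highest list median, a log2 ratio of 1.98 (1.53 with bounds, 1.01 to 2.14 under the alternatives), above all 10000 random lists. At least 1.5-fold higher were 16 of 21 measured members, and none was 1.5-fold lower. H2BC21 was 11.5-fold higher, H2AC6 8.95-fold higher and H3C10 8.30-fold higher. H2AC18, whose sequence is nearly identical to that of H2AC19 and whose assignment is therefore uncertain, had a log2 ratio of 3.46. The other 5 members, named after their values were seen, were H2BC6 (bound 0.52), H3-3A (0.04), H3-3B (0.08, but −0.46 with the series matrix values), H2AZ1 (−0.27, but 0.55 with median centring) and H4C3 (−0.05, but 0.72 with median centring and 0.13 with the series matrix values). H4C3, H2AZ1 and H3-3A lay near the top of the scale on both arrays, where ratios are compressed, so their ratios do not show that they differed from the other members. The transcripts of H3-3A, H3-3B and H2AZ1 carry a poly(A) tail. Small structural RNAs, most of which have none, were higher as well, with a median log2 ratio of 1.49 over 148 genes.

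The heat shock proteins, chaperones of unfolded proteins, had a median log2 ratio of 0.37 (percentile 99.99, 0.14 to 0.73 under the alternatives), with 9 of 28 members at least 1.5-fold higher and 2 lower. Besides HSPA6, the cochaperone DNAJB1 had a log2 ratio of 3.58, and HSF1, the transcription factor of the heat shock response, was at least 3.99-fold higher. HSPA1B, nearly identical to HSPA1A and so uncertain, was 3.70-fold higher. The hypoxia and HIF targets had a median log2 ratio of 0.41 (0.09 to 0.67 under the alternatives), above all 10000 random lists, with 13 of 34 members higher and 2 lower. Among them the glucose transporter SLC2A3 was 3.64-fold higher, JMJD6 2.99-fold, FAM162A 2.65-fold and the histone demethylase KDM3A 2.41-fold. The p53 targets and cyclin-dependent kinase inhibitors had a median log2 ratio of 0.26 (percentile 99.26), with 7 of 28 members higher and 4 lower. This list did not stand apart with no filter on detection (0.15, percentile 95.3), and its median turned to −0.17 with the series matrix values, still at percentile 97.9, and was 0.41 at most. MDM2, the ubiquitin ligase of p53, was 3.13-fold higher and the kinase inhibitor CDKN2D 3.05-fold higher, while the 2 probes of BAX, a promoter of apoptosis, disagreed (log2 ratios of −1.16 and 0.49).

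The T cell activation and cytokine genes had a median log2 ratio of 0.55 (0.44 with bounds, percentile 99.9), which was 0.09 with the series matrix values, 0.15 with no filter on detection, 0.24 without background correction and at most 0.73, with 6 of 19 measured members at least 1.5-fold higher and 2 lower. The cytokine signalling inhibitor SOCS1 was 4.83-fold higher, the kinase PIM1 4.51-fold higher and the early activation marker CD69 3.15-fold higher. IL7R, the receptor for interleukin 7, was 4.99-fold lower. The cytosolic ribosomal proteins had a median log2 ratio of 0.05 (percentile 99.84), which was 0.82 with median centring and 0.23 with the series matrix values. Their median control signal was 62982.9, near the highest signal of that array (73762.5), so most of these ratios come from the top of the scale, where they are compressed. RPL14 was 3.07-fold higher and the 2 probes of RPL37 disagreed (log2 ratios of 1.38 and −0.54), while RPL7 and RPL28 were 1.94-fold and 1.79-fold higher.

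Genes of DNA replication and S phase had the lowest list median, a log2 ratio of −0.65 (−0.63 with bounds, −1.04 to −0.46 under the alternatives), below all 10000 random lists. Of 48 measured members, 28 were at least 1.5-fold lower and 2 higher. E2F2, a transcription factor that drives S phase entry, was 4.52-fold lower, the ribonucleotide reductase subunit RRM2 4.08-fold lower, and the repair and replication genes UNG and FEN1 2.99-fold and 2.94-fold lower. The list of G2 and mitosis genes did not stand apart (median log2 ratio −0.06, percentile 50.64). Of its 50 members, 12 were lower and 2 higher, with KIF20B 2.88-fold lower, the spindle gene ASPM 2.75-fold lower, KIFC1 2.27-fold lower and the centrosome kinase NEK2 2.36-fold higher.

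The ribosome biogenesis and nucleolus genes had a median log2 ratio of −0.36 (percentile 0.44, −0.76 to −0.15 under the alternatives), with 19 of 44 members at least 1.5-fold lower and 1 higher, but did not stand apart over genes detected on both arrays (−0.26, percentile 2.82). NOP56, a core protein of small nucleolar ribonucleoproteins, had a log2 signal of 14.73 on the control array and 12.73 on the Me6TREN array. RRP9 was at least 3.21-fold lower, POLR1B, a subunit of RNA polymerase I, at least 2.67-fold lower and RRP12 2.42-fold lower. The proteasome genes, which encode the main protease for ubiquitin-tagged proteins, had a median log2 ratio of −0.42, below all 10000 random lists, although this median was 0.03 with median centring, still below all random lists. Of 32 members 8 were lower and 1 higher, and PSMC4, an ATPase of its regulatory particle, was 3.16-fold lower. PSME3 was 1.65-fold lower and PSMD6 1.64-fold lower, as was PSMB1 (log2 ratio −0.71, against 0.07 with median centring).

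The endoplasmic reticulum chaperone and unfolded protein response genes had a median log2 ratio of −0.46 (percentile 0.44, −0.87 to −0.285 under the alternatives), with 10 of 29 members at least 1.5-fold lower and 4 higher. HSPA5, the main chaperone of that compartment, was 6.11-fold lower and CRELD2 2.42-fold lower, while DNAJB9 and DNAJC3 were 2.96-fold and 2.26-fold higher. ATF4 and amino acid response genes had a median log2 ratio of −0.32 (percentile 0.88), with 17 of 43 members lower and 5 higher, but the list did not stand apart with median centring (0.14, percentile 11.82) or with the series matrix values (−0.46, percentile 11.32). The amino acid transporters SLC7A5 and SLC7A1 were 5.76-fold and 5.52-fold lower and the transcription factor ATF5 5.48-fold lower, against the higher PPP1R15A, which is also on this list. The BCL2 family and apoptosis genes had a median log2 ratio of −0.58 (percentile 0.92), with 13 of 33 lower and 6 higher, but the list stood apart under 3 of the 9 alternatives only (−0.73 to −0.24). With bounds its median was −0.29, inside the random range of −0.505 to 0.185, which was drawn without bounds. BCL2L11 and HRK, which promote apoptosis, were 8.49-fold and 4.47-fold higher, and FADD, the adaptor of death receptors, was 4.65-fold lower. The probes of BCL2, an inhibitor of apoptosis, disagreed, with log2 ratios from −1.54 to 0.57.

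**Figure D3:**
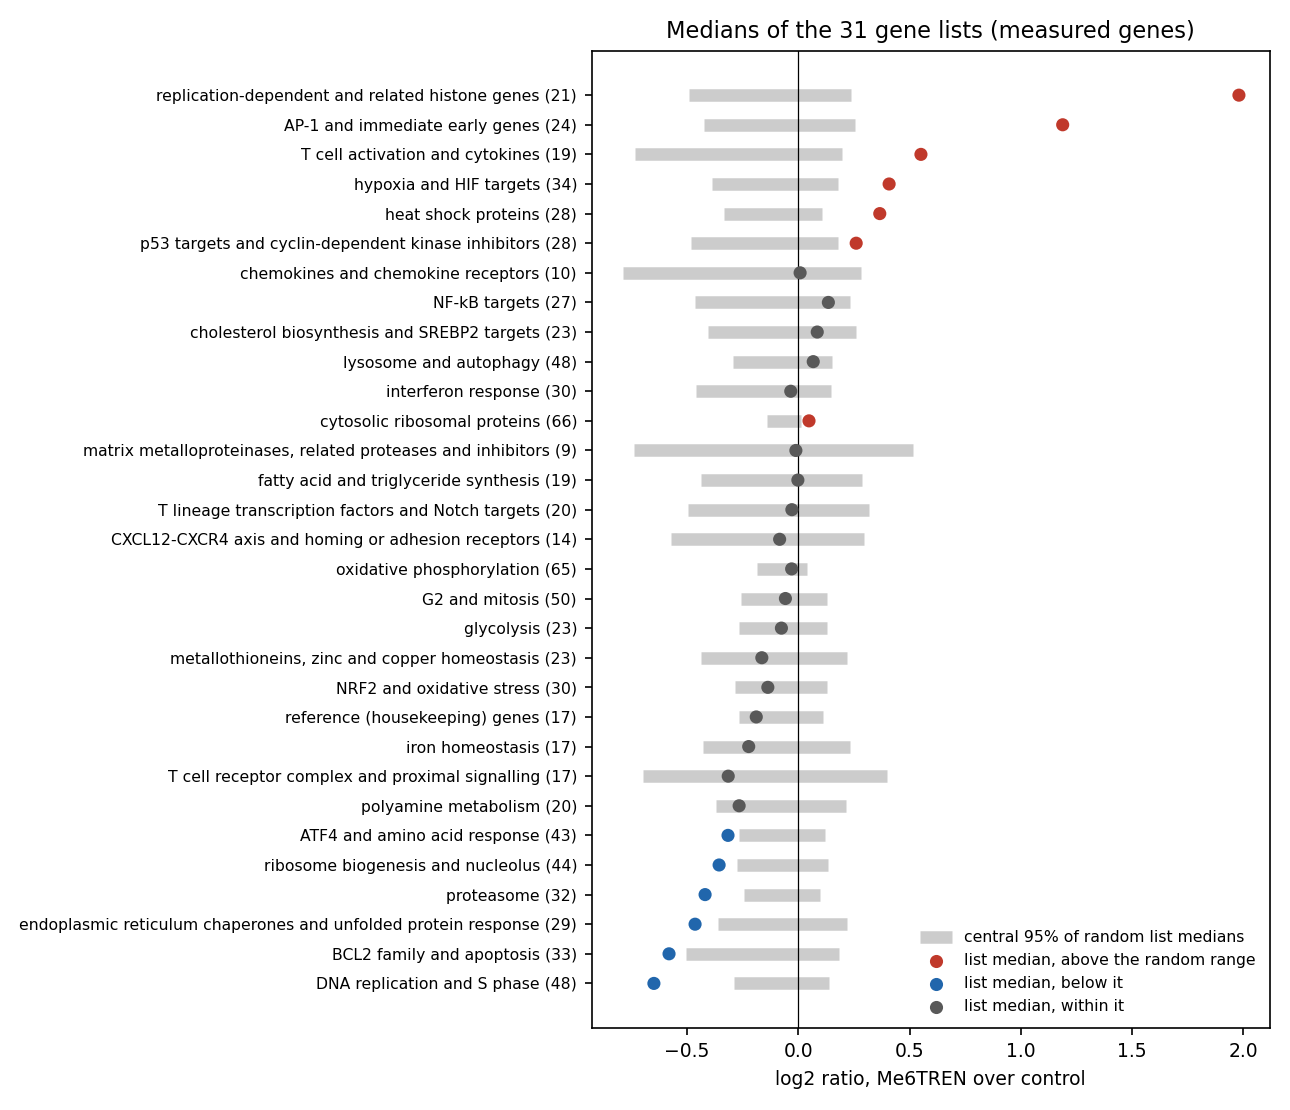
Median log2 ratio (Me6TREN over control) of each of the 31 gene lists, with the number of measured genes in brackets and grey bars for the central 95% of the medians of 10000 random lists matched on mean signal. The histone list (1.98) and the AP-1 list (1.19) lie farthest above the bars and the DNA replication list (−0.65) lies lowest; the medians of the p53, ATF4 and proteasome lists change sign under another scaling.

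**Figure D4:**
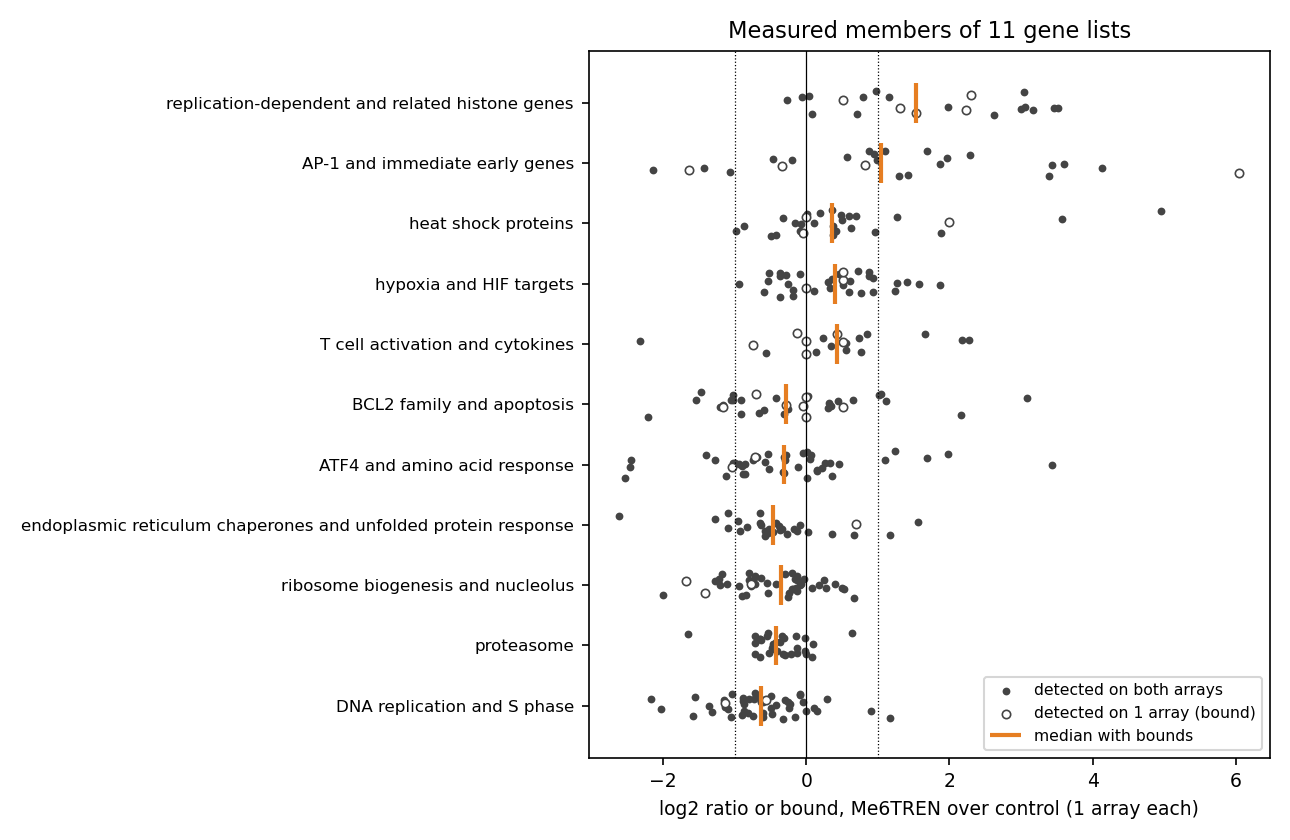
Log2 ratio of each measured member of 11 gene lists, filled where detected on both arrays and open, at the bound, where detected on 1 array; orange bars mark medians with bounds and dotted lines 2-fold differences. All but 5 of the 21 histone genes lie at least 1.5-fold higher, while 28 of the 48 DNA replication genes lie at least 1.5-fold lower; the sign of the ATF4 and proteasome medians turns with median centring.

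The lists tied to the known use of Me6TREN did not stand apart from random lists. In the list of the CXCL12-CXCR4 axis and homing receptors (median log2 ratio −0.08, percentile 58.73), 2 of 14 members were at least 1.5-fold higher and 2 lower. CXCL12 was not detected on either array. The brightest probe of its receptor CXCR4 gave a log2 ratio of −0.55 and another detected probe 0.46. ACKR3, the other receptor of CXCL12, was 4.41-fold higher and the adhesion protein CD99 1.99-fold higher, whereas the integrin ITGA4 was 1.96-fold lower and the signalling protein VAV1 1.86-fold lower. Of the matrix metalloproteinases and related proteases (median −0.01, percentile 61.85), 1 of 9 members was higher and 1 lower. MMP2 was not detected, MMP9 had a log2 ratio of −0.36 and the inhibitor TIMP1 0.33, which turned to −0.13 with the series matrix values. The membrane proteases ADAM9 and ADAM19 were 3.70-fold higher and 2.14-fold lower. Among chemokines and their receptors (median 0.01, percentile 84.98), 2 of 10 were higher and 1 lower. CCR7, a receptor that guides lymphocytes to lymph nodes, was 3.54-fold lower, CXCL10 1.51-fold higher and CCL22 at least 1.91-fold higher, and CXCR5 had a log2 ratio of 0.44 that turned to −0.12 with the series matrix values.

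Lymphocyte signalling lists showed members in both directions. The T cell receptor list (median −0.31, percentile 27.72) had 3 of 17 members higher and 5 lower. BCL10, an adaptor of antigen receptor signalling, was at least 2.67-fold lower by its brightest probe. Its other probe, also detected on the control array alone, had a log2 ratio of −0.13. The costimulator CD28 was 1.88-fold higher and the phosphatase PTPRC 1.75-fold lower. Among T lineage transcription factors and Notch targets (median −0.03, percentile 62.04), 5 of 20 were higher and 4 lower. HES1, a target of Notch, was 6.71-fold higher and the inhibitor of differentiation ID2 4.33-fold higher, while RUNX3 was 3.59-fold lower and RUNX1 at least 3.43-fold lower. Of the NF-kB targets (median 0.14, percentile 92.11), 7 of 27 were higher and 5 lower, with NFKBIZ 2.90-fold higher, TNFAIP8 3.57-fold lower and CD83 2.17-fold lower. The interferon response genes (median −0.03, percentile 78.26) had 4 of 30 members higher and 2 lower, with GBP2 2.66-fold and HLA-F 1.99-fold higher, SP100 at a log2 ratio of −1.32 and IFIT2 at least 1.70-fold lower.

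Lists of metal and polyamine handling also did not stand apart. Among metallothioneins and genes of zinc and copper homeostasis (median −0.16, percentile 36.62), 2 of 23 were higher and 6 lower, with the zinc exporter SLC30A1 3.82-fold higher, the zinc-sensing factor MTF1 2.03-fold lower and the importers SLC39A10 and SLC39A14 1.82-fold and 1.75-fold lower. The iron homeostasis genes (median −0.22, percentile 20.16) had 3 of 17 members higher and 4 lower, with the transferrin receptor TFRC 2.76-fold lower, the iron-sulfur gene NFS1 at least 3.83-fold lower, and ALAS1 and SLC25A38 of haem synthesis 2.13-fold and 1.92-fold higher. In polyamine metabolism (median −0.27, percentile 9.84), 3 of 20 were higher and 7 lower. SAT1, which starts polyamine breakdown, was 4.65-fold higher and SAT2 2.22-fold higher, whereas AMD1 of polyamine synthesis was 2.49-fold lower and the oxidase PAOX 2.04-fold lower.

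In metabolism, glycolysis (median −0.08, percentile 38.38) had 3 of 23 members higher and 3 lower. Besides SLC2A3, ALDOC was 1.84-fold and PFKFB4 1.64-fold higher, and PGD of the pentose phosphate pathway was 1.81-fold lower. Of the oxidative phosphorylation genes (median −0.03, percentile 68.58), 61 of 65 lay within 1.5-fold. NDUFC2, ATP5F1E and NDUFC1 were 1.99-fold, 1.76-fold and 1.68-fold higher, and CYCS, cytochrome c, was 2.06-fold lower. Cholesterol biosynthesis and SREBP2 targets (median 0.09, percentile 81.02) had 4 of 23 members higher and 2 lower. MYLIP, which degrades the LDL receptor, was 5.58-fold higher, SREBF2 1.99-fold and MSMO1 1.72-fold higher, and SC5D was 2.88-fold lower. The fatty acid and triglyceride synthesis genes (median −0.002, percentile 63.5) had 3 of 19 members higher and 3 lower, with the lipid droplet gene HILPDA 4.59-fold and MID1IP1 1.62-fold higher, GPAM 2.90-fold lower and ACACB at least 1.65-fold lower.

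Among lysosome and autophagy genes (median 0.07, percentile 89.06), 13 of 48 were higher and 8 lower, with the sialidase NEU1 3.09-fold and FLCN 2.61-fold higher, and the cathepsin CTSZ 3.40-fold and the autophagy kinase ULK1 2.82-fold lower. The NRF2 and oxidative stress genes (median −0.14, percentile 23.9) had 4 of 30 members higher and 10 lower. TXNRD1, thioredoxin reductase, was 3.44-fold lower, SRXN1 2.57-fold lower, KEAP1, the repressor of NRF2, 2.31-fold lower and SESN3 3.24-fold higher. Of 17 reference genes (median −0.19, percentile 10.9), none was higher and 3 were lower. TBP was 1.77-fold and GUSB 1.57-fold lower, and TUBB had a log2 ratio of −0.74, against 0.04 with median centring. GAPDH and ACTB had log2 ratios of −0.11 and −0.07, and LDHA −0.37, which turned to 0.68, 0.68 and 0.46 with median centring. The probes used for GAPDH and ACTB lay near the top of the scale, where ratios are compressed. Their other probes gave log2 ratios of −0.13 and −0.38 for GAPDH and −0.63 and −0.28 for ACTB. The median of 17 of the 18 lists that did not stand apart changed sign under at least 1 alternative, a count that says little about the lists because the scalings shift the median of all genes from −0.12 to −0.43 or 0.08.

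No replicate bounds these values, and the nearest measure of precision is the agreement between probes of a gene. Among 1912 genes with several probes detected on both arrays, the median standard deviation of the log2 ratio between probes was 0.23, and probes went both ways in 25.3% of the 491 genes with a probe past 2-fold.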

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

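The tests in this part were chosen after the result was seen, except the test of the signal share of small RNAs. Some tests replaced ones already run. For RNA without a poly(A) tail, the share of small RNAs above 0 (94.6%) and then the median of the polyadenylated histone genes alone had both counted for it. For a single brightness factor, the span over all 10 bins (0.80), whose ends are bounded by detection and saturation, had counted against it. For the small nucleolar RNA host genes the criterion was made stricter, and the first one had counted against that explanation. For a mainly T-lineage culture, the signal levels replaced 2 counts of detected T-restricted genes, of which the count on both arrays (4 of 18) argued against it and the count on at least 1 array (9 of 18) left it open. Probes with no gene symbol of their own enter no comparison of the report, and they held a signal: 544 of 3711 detected ones were at least 2-fold higher on the Me6TREN array and 163 at least 2-fold lower, without an explanation tested here.

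Both arrays detected B lineage genes and few T-restricted ones, against the label of a T cell line. Wrong probe names are argued against by the cytosolic ribosomal proteins, of which 98.5% were detected on both arrays. A mainly T-lineage culture with some B-lineage cells is argued against by the median signals of the 18 T-restricted genes. On the control array the median was 309.1 (95% interval up to 460.3), against 1912.0 for the fixed B cell markers and a lowest detected signal of 333.4. On the Me6TREN array it was 309.5 (up to 374.3), against 1106.4 and 350.5. Both intervals reach above the lowest detected signals, and signals of different probes, which differ in brightness, are compared. These 18 genes were picked after their values were seen, while the intervals treat them as a random draw of genes. The whole T cell receptor list, fixed in advance, had a median control signal of 309.5. It contains the 18 genes and so is not an independent check. The brightest of the 18 had a control signal of 1218.7, and a small share of T-lineage cells stays open. Mainly B-lineage cells on both arrays, through another line or a mislabelled culture, stay open, since the 80% of 5 fixed B cell markers (none in another list) detected on both arrays are part of the pattern and do not test its source. CD79B, the brightest of them, had a control signal of 45069, and no biological explanation was tested.

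Small structural RNAs and clustered histone genes were higher on the Me6TREN array, and many of these transcripts have no poly(A) tail. A lift of dim probes by the normalization is argued against, since the small RNA median lay 1.62 above that of random genes of the same mean signal on the log2 scale. For the small nucleolar RNAs, higher transcription of host genes stays open: the SNHG and GAS5 host genes had a median log2 ratio of 0.43 (robust standard deviation 0.52) against 1.35, a gap of 0.92 that was within that setting's standard deviation with median centring (0.54), with the series matrix values (0.39) and with no filter on detection (0.15). More RNA without a poly(A) tail labelled on the Me6TREN array stays open: 8 polyadenylated histone genes had a median log2 ratio of 0.06, but H2AJ among them was at 3.57 and H1-10 at 1.94, and H3-3A and H2AZ1 lay near the top of the scale. An effect of Me6TREN on these RNAs stays open too and untested, since treatment and array coincide.

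Before scaling, background-corrected signals were lower over most of the range on the Me6TREN array. The medians of the log2 ratio over signal bins 2 to 9 of 10 spanned 0.41, from −0.80 to −0.39. By the limit set for it, this span counted against a single brightness factor. However, the value of −0.39 is that of bin 9, next to the brightest bin, where signals are compressed. Bin 2, next to the dim end, was at −0.58, and bins 3 to 8 ran only from −0.80 to −0.62. The span cannot separate a single factor from such compression, so a single factor stays open. Signal taken up by small structural RNAs stays open. The share of the total on their 316 named probes was only 0.61 percentage points higher (0.88% against 0.27%). By the limit set before the result was seen, this gain counted against the explanation. The share still cannot decide the question, because probe signals are compressed at the top of the scale and do not measure the share of labelled RNA. Probes without a symbol were also left out. A lower messenger RNA content of treated cells and a lower labelling yield both stay open and untested with 1 array per group.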

How the results depend on the processing

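All 9 alternatives were planned and run, and no replicate could be left out with 1 array per group. The main counts were 634 genes higher and 935 lower at 2-fold. They were 292 and 436 without background correction, 391 and 612 with normexp over all probes, and 283 and 2332 with the series matrix values. With no filter on detection 1464 were lower. In that setting more genes enter, and genes detected on 1 array only count by their plain ratio in place of the bound. Of the list medians, 105 of 117 stayed apart from random lists in the same direction. The BCL2 list no longer did without background correction (−0.24), with normexp over all probes (−0.30), with the series matrix values (−0.73), with genes detected on both arrays (−0.37), with the mean of probes (−0.40) and with an offset of 50 (−0.46). The ATF4 list was at 0.14 with median centring and −0.46 with the series matrix values, the proteasome list at 0.03 with median centring, and the p53 list at −0.17 with the series matrix values and 0.15 with no filter. The ribosome biogenesis list was at −0.26 over genes detected on both arrays. The proteasome and p53 medians that changed sign still lay outside the random range on their main side. The causes of these changes were not tested. The 126 named genes past 2-fold kept their direction in all 1119 values. That says little, because most were named for their large ratios, the alternatives reuse the same 2 arrays and a bound cannot change sign. Of 1606 values of named genes, 77 moved by more than the robust standard deviation at that signal. Signals near the detection limit, with 1250 genes detected on the control array alone and 326 on the Me6TREN array alone, limit the ratios of dim genes. No paired analysis was possible because each group has 1 array and no test was made.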

Other observations

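The gene classes and genes in this part were chosen after the values were seen. Signals of small structural RNAs were higher on the Me6TREN array as a class. Of 148 measured genes, 140 had a log2 ratio above 0 (94.6%), 99 were at least 2-fold higher and 1 at least 2-fold lower, and the median log2 ratio was 1.49, between 0.55 and 1.68 under the alternatives. RN7SK, which restrains transcription elongation, was 16.7-fold higher, RMRP, of mitochondrial and ribosomal RNA processing, at least 11.8-fold higher, the spliceosomal RNA RNU11 13.2-fold higher, the ribosomal RNA RNA5S9 11.2-fold higher, RPPH1 of transfer RNA processing 5.40-fold higher and the Y RNA RNY4 6.71-fold higher. RN7SL1 of the signal recognition particle had a log2 ratio of 0.07 and SNAR-A1 of −0.29, which turned to 0.13 with median centring. Clustered histone genes outside the fixed list had log2 ratios above 0 in 23 of 23 detected cases, with a median of 1.46, which was 0.77 without background correction, 0.59 over 51 genes with no filter on detection and 1.65 at most.

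Solute carriers, the transporters of amino acids, sugars, ions and other small molecules, had a median log2 ratio of −0.44 over 141 genes, below all 2000 matched random lists, and it stayed below 0 under the alternatives (−0.81 to −0.09). The chloride cotransporter SLC12A2 was at least 3.94-fold lower, while SLC4A8 and the inositol transporter SLC5A3 were 7.74-fold and 4.99-fold higher. Long non-coding RNA genes had a median log2 ratio of 0.35 over 147 genes (0.0 to 0.55 under the alternatives), with 25 at least 2-fold higher and 10 lower. LINC00115 was 13.6-fold higher and LINC00294 had a log2 ratio of −2.15. Among the B lineage genes, the receptor TLR10 had a log2 ratio of −2.69, the kinase SYK of −1.27 and TCL1A, a coactivator of AKT signalling, of 1.13.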
